A study of Mus musculus with 2 samples.

How the data were processed

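The samples were 2 RNA preparations from CD4 T cells sorted from mouse spleen cell cultures, 1 for the naive-only culture and 1 for the co-culture with anergic cells, each hybridised to 1 array. Per the labels' protocols, total RNA was amplified with the Ovation RNA Amplification System V2, and the amplified cDNA was labelled with Cy3 by an enzymatic labelling kit made for genomic DNA. Amplification can alter the relative levels of transcripts, and with 1 array per group its effect cannot be measured. Groups were taken from the sample titles. Both arrays were on the same slide and scan, so slide and scan do not separate the groups.

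Per the file headers, spot intensity was extracted with Agilent Feature Extraction 10.7.1.1, whereas the submitters' processing notes name version 9.5.1.1; which of them made the deposited values is not settled here. The processed intensity, per the file headers, is a background-subtracted linear value with an error from the software's error model. The deposited value table holds a linear intensity that the authors normalized. Its sorted columns match each other within 0.0369%, as quantile normalization gives, and the median was 14.5 in both columns. Its direction and scale were settled against the scanner values: ranks matched on each array (Spearman correlation 1), and its log2 difference correlated at 0.999 with the scaled difference across probes above background. What else the authors did to this table is not given in the sources used here.

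Each array held 62976 spots, of which 59305 were noncontrol spots of 55681 probes. No spot was saturated. The software marked 3 and 1 spots as non-uniform and 185 and 169 as population outliers on the naive-only and co-culture arrays. These were kept in the main values and left out in an alternative. Among 399 probes printed in 10 spots, 233 and 230 were above background, and the median SD of their repeated spots was 0.061 and 0.055 (log2) on the naive-only and co-culture arrays. Such repeats measure spot noise only, and the number of arrays limits the precision of every comparison.

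The main value was log2 of the processed signal, averaged over a probe's spots, minus the array's 75th percentile over noncontrol probes (299.4 and 301.3 intensity units). Differences are co-culture minus naive-only. A gene was represented by its probe with the highest mean level over both arrays, a choice that does not use the difference but can favour a bright cross-hybridising probe. It counted as measured where that probe was well above background on both arrays by the software's call. The 3580 genes with at least 2 measured probes had a median SD of 0.128 between probes. Of 349 genes past 2-fold with at least 2 measured probes, 21 had a probe of the opposite sign. A gene above background on 1 array only was given a bound, its level there against the higher of the lowest level well above background and its own signal on the other array. The error beside a difference combines the software's errors of both arrays and is technical only.

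Gene names came from the array files. Of the noncontrol probes, 36743 had a gene name and 18938 had none and were not used. The accessions of 27235 named probes were found in a RefSeq table (assembly GRCm38.p6, used for names only), which changed 2838 symbols, and 9508 probes kept the file's name. This gave 27665 genes. Probe positions are on mm9, per the file headers; exon and UTR annotation of that build was not used here.

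Genes were counted at a log2 difference of 1 or more in size. Before the data were examined, 36 gene lists were fixed, 24 of T cell programmes and 12 of other cell types. Each list's median over measured members was placed among the medians of 10000 random lists of the same size matched on deciles of mean signal, and was called apart below percentile 2.5 or above 97.5. This describes these arrays: genes of a list are regulated together and are not replicates, so no p-value was computed. By this measure 11 lists were higher and 15 lower. Some lists share genes, so these are not separate results. Of the 35 cytokine and chemokine genes, 22 are in another fixed list, as are 10 of the 23 regulatory T cell genes. Each median also had a bootstrap interval over members, between percentiles 2.5 and 97.5. Another 2 lists, of hypoxia targets and STAT5 targets, were added after the data were seen.

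Genes were named by a rule fixed before the data were examined. It took the 12 largest differences in each direction among genes with a proper symbol that were not receptor or immunoglobulin segments, and up to 4 members past 2-fold in each fixed list. It also took 17 genes set in advance whatever their value, and up to 5 of the largest bounds per direction. The few genes named outside it were chosen after their values were seen, and the text marks them. Of the genes the rule took, 1 is not reported here.

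The calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, R 4.3.3 with limma 3.58.1 and, for figures, matplotlib 3.10.9. They were tested on simulated data with this design. Of 100 genes changed 3-fold, 99 passed 2-fold, as did 100 of 100 changed 6-fold and 2 of 14176 unchanged genes, and 10 of 200 unshifted lists fell outside the percentile limits. The simulation holds technical error only. The alternatives set in advance were normexp background correction (offset 50), quantile normalization, scaling to the median or to the 75th percentile of detected probes, loess on signal (span 0.3), no filter on dim probes, a stricter filter, the mean over probes, marked spots left out, the deposited value table, random lists not matched on signal, and list members above background on either array. A filter to the brighter measured genes was added after seeing the data.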

Results

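Gene expression was measured in CD4 T cells sorted from mouse spleen cell cultures after 24 h with ovalbumin (OVA, 0.1 mg/mL), the antigen recognised by the transgenic T cell receptor of the female donor mice. In the naive-only culture, spleen cells were stimulated at 2500000 cells/mL. In the co-culture, naive spleen cells at 1250000 cells/mL were mixed with an equal number of spleen cells stimulated earlier with TSST-1 (0.1 μg/mL), a bacterial superantigen, which the labels call anergic, that is, poorly responsive to antigen. The labels do not say whether the sort parted the naive cells from the pre-stimulated ones, so the co-culture array may hold RNA of both. Each group had 1 single-colour array, so no difference below has a replicate check and no test between the groups was possible. The arrays held 55681 noncontrol probes, of which 25744 (46.2%) were well above background on the naive-only array and 25136 (45.1%) on the co-culture array.

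The series' design text sets naive cells cultured with anergic cells against naive cells alone. Of 14378 named genes above background on both arrays, 1110 (7.72%) were at least 2-fold higher on the co-culture array and 796 (5.54%) at least 2-fold lower. Genes of mitosis, Il4, Il10 and Gzmb were higher on the co-culture array. Il2, Il3, Il22, genes induced by interferon and markers of B cells were lower. At 4-fold, 309 genes were higher and 225 lower. The median log2 difference over all measured genes was -0.05, with an interquartile range of -0.37 to 0.33, and the levels on the arrays correlated across genes with r = 0.967 (genes are not independent replicates). The median technical error of a log2 difference was 0.20, from the scanner software's error model, which leaves out the variation between cultures. Bright genes such as Il2ra and Ifng had the same error of 0.204, so it is not a spread measured gene by gene.

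**Figure D1:**
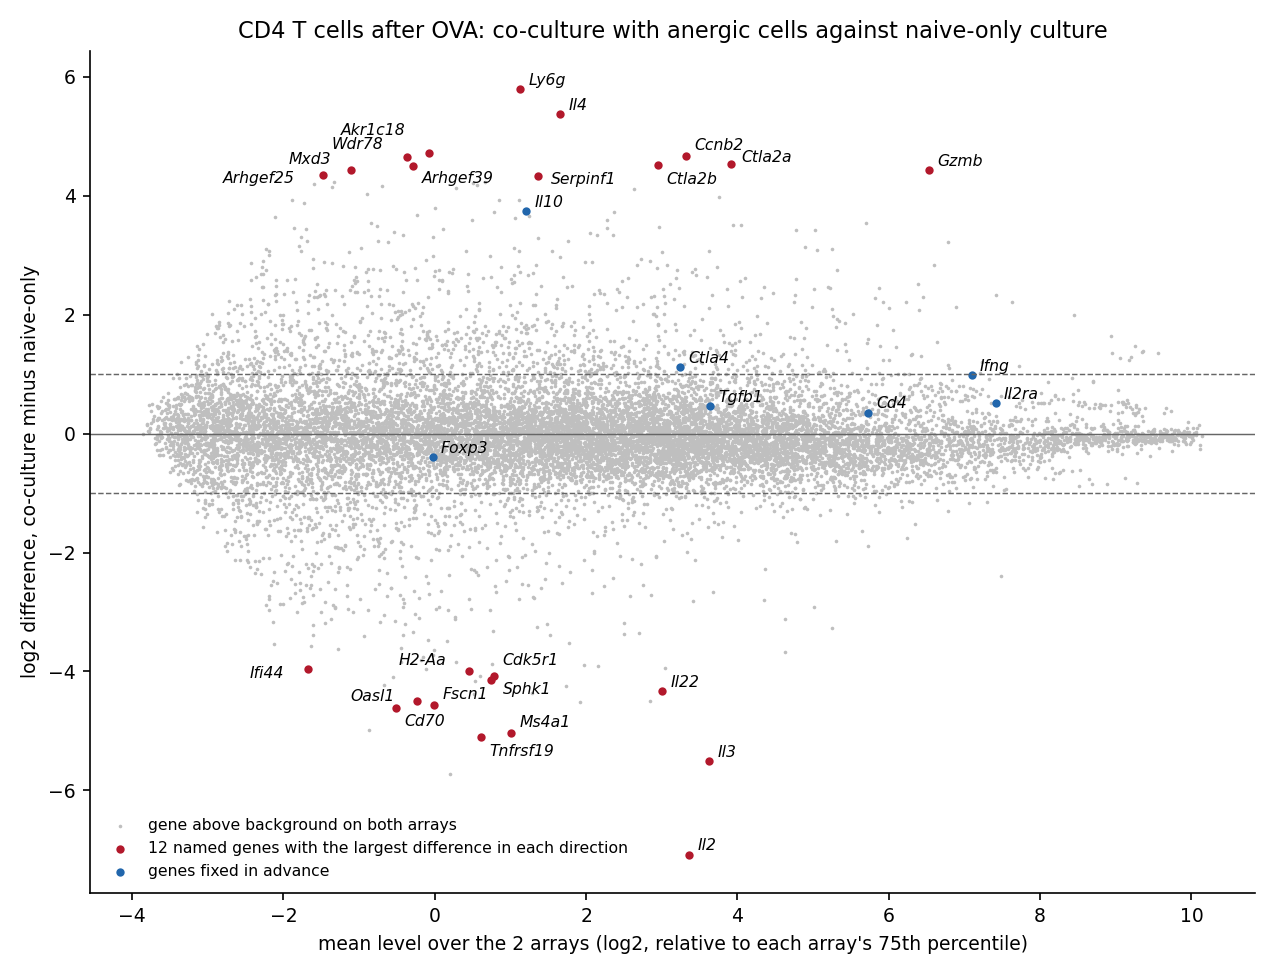
Log2 difference (co-culture minus naive-only) against the mean log2 level over both arrays, relative to each array's 75th percentile, for the 14378 genes above background on both. Dashed lines mark 2-fold, red points the 12 named genes with the largest difference in each direction (Il2 at -7.08 and Ly6g at 5.80 are the extremes) and blue points genes fixed in advance.

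Il2, the T cell growth factor gene, had the largest difference among the named genes that were lower. Its level was 6.90 on the naive-only array and -0.18 on the co-culture array (log2, relative to the array's 75th percentile), a log2 difference of -7.08 ± 0.21 (technical error), or 135-fold lower. Its probe lies on chromosome 3 at 37020012 to 37020071 (mm9). Il3, a growth factor for blood cell precursors, was 45.6-fold lower and Il22, a cytokine that acts on epithelia, 20.1-fold lower. Il4, the signature cytokine of type 2 helper T cells (probe on chromosome 11 at 53426076 to 53426135), was 41.4-fold higher, with a log2 difference of 5.37 ± 0.21. Il10, an anti-inflammatory cytokine (chromosome 1, 132920943 to 132921002), was 13.3-fold higher at 3.74 ± 0.21. Ifng, the signature cytokine of type 1 helper T cells, was 1.99-fold higher at 0.99 ± 0.20 (1.03 to 1.09 under 5 other scalings, among them the deposited table), and Tgfb1 differed by 0.46 ± 0.20. Of the 32 secreted cytokines and chemokines measured on both arrays, 6 were at least 2-fold higher and 10 at least 2-fold lower. The list median was -0.41, at the 0.02 percentile of medians of 10000 random lists matched on signal. When only the brighter measured genes were kept, the cytokine median was -0.045. Markers of B cells (median -1.74) and dendritic cells (median -0.86) were lower on the same array, and Ccl22, which the dendritic cell list also holds, was above background only on the naive-only array.

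**Figure D2:**
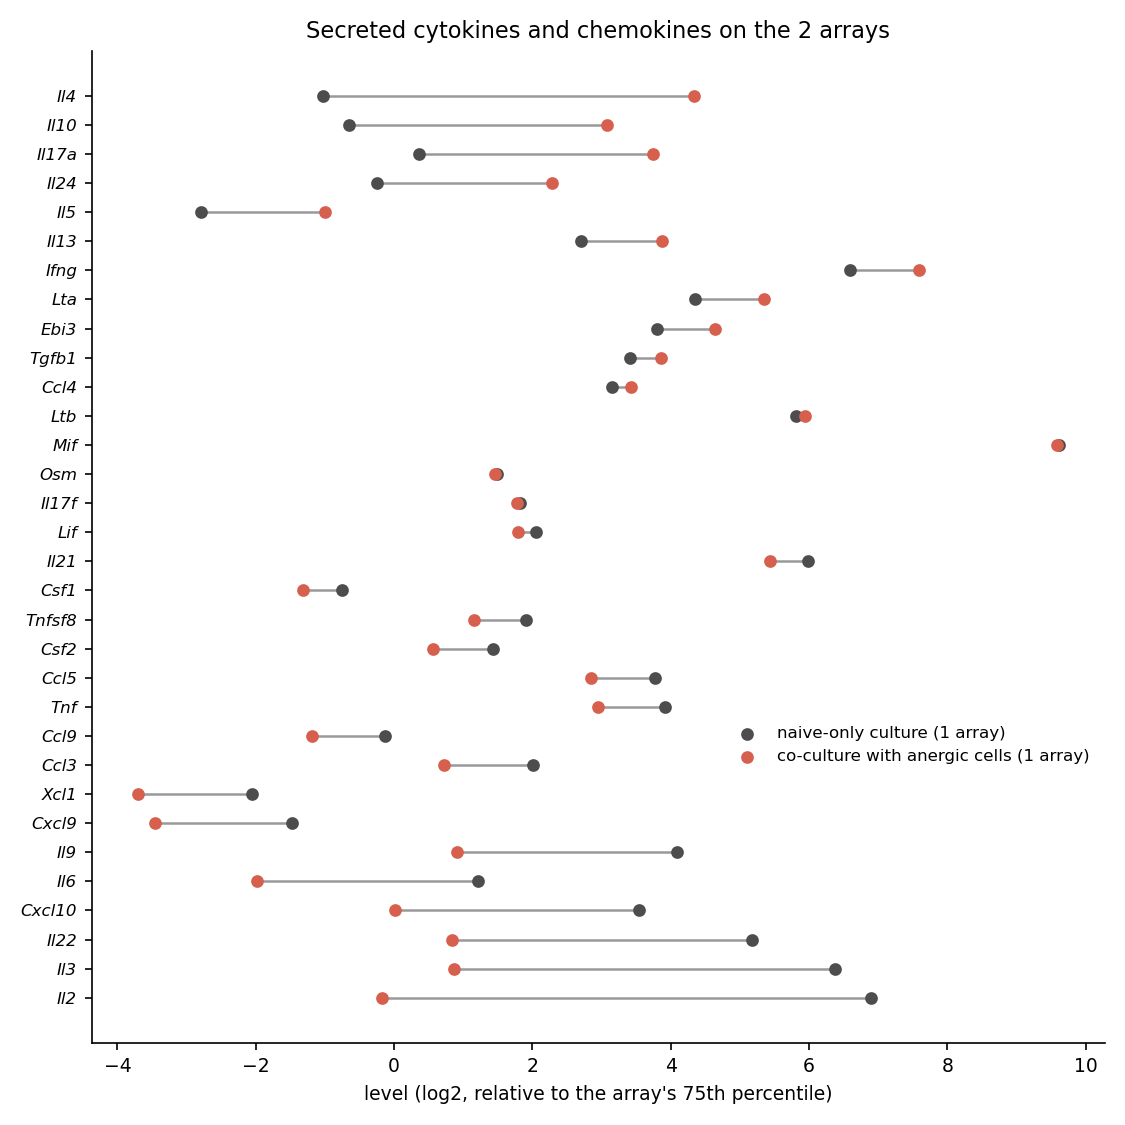
Levels of the 32 secreted cytokines and chemokines above background on both arrays (log2, relative to the array's 75th percentile), 1 point per array, joined by gene. Points compare the arrays within a gene, not genes with each other. Il4 and Il10 lie higher on the co-culture array by 5.37 and 3.74, and Il2 and Il3 lower, at -7.08 and -5.51.

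The other genes with the largest positive differences were Ly6g, a surface protein of the Ly6 family (5.80 ± 0.22, 55.6-fold), Akr1c18 (4.72), the mitotic cyclin gene Ccnb2 (4.67), Wdr78 (4.65), Ctla2a (4.54) and Ctla2b (4.52), Arhgef39 (4.49), the Max-binding repressor gene Mxd3 (4.43), Arhgef25 (4.35) and Serpinf1 (4.34). Gzmb, which encodes the granule protease granzyme B, was 21.5-fold higher at 4.43 ± 0.20. Ctla2a and Ctla2b are near-identical copies, and Ly6g rests on 1 probe in a family of similar genes, so these values are uncertain as to the gene. With normexp background correction, 31 of 134 named genes had folds smaller by over 1.5 times, such as Ly6g at 31.0-fold, Arhgef25 at 6.29-fold, Mxd3 at 7.32-fold and Ifi44 at 5.17-fold. The remaining genes with the largest negative differences were Tnfrsf19 (-5.10), the B cell surface gene Ms4a1 (-5.03), the costimulatory ligand gene Cd70 (-4.61), Fscn1 (-4.56), the interferon-induced Oasl1 (-4.49), Sphk1 (-4.14), Cdk5r1 (-4.07), the class II antigen presentation gene H2-Aa (level 2.46 on the naive-only and -1.54 on the co-culture array) and the interferon-induced Ifi44 (-3.96).

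Genes above background on 1 array only have a bound. Of those detected only on the co-culture array, Vldlr was at least 36.5-fold higher there, Cpne6 at least 28.2-fold, Eya2 at least 18.0-fold, Neil3 at least 16.6-fold and Xdh at least 16-fold. Of those detected only on the naive-only array, the collagen gene Col1a2 was at least 25.9-fold lower on the co-culture array, the chemokine gene Ccl22 at least 22.0-fold, Syt13 at least 17.5-fold, Idi2 at least 15.7-fold and Crygc at least 15.5-fold. With normexp, these bounds were smaller, from 4.35-fold for Neil3 to 9.70-fold for Vldlr. In all, 825 genes were detected only on the co-culture array and 1026 only on the naive-only array.

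Genes of mitosis were higher almost without exception. Of 41 measured members, 39 were at least 2-fold higher and none was lower, and the remaining 2, Cep55 (0.17) and Cks2 (0.74), which are named because they are the exceptions, were also positive. Ccnb2 was 25.5-fold higher, the centromere histone gene Cenpa 17.3-fold, the mitotic ubiquitin-conjugating enzyme gene Ube2c 15.8-fold and the spindle gene Nusap1 13.2-fold. The list median was 2.44, or 5.44-fold, above the medians of all 10000 random lists. Genes of DNA replication and S phase had a median of 0.071, with 4 of 39 at least 2-fold higher and none lower. These were the thymidine kinase gene Tk1 (2.36), E2f2 (1.53), the ribonucleotide reductase gene Rrm2 (1.24) and the cyclin gene Ccne1 (1.09). That median lay at the 98.4 percentile of matched random lists, and at the 89.2 percentile of lists not matched on signal.

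Genes of ribosome biogenesis and targets of Myc, a growth-promoting transcription factor, were lower as a group. All 41 measured members had negative differences, 8 of them at least 2-fold, with a median of -0.72, below all 10000 random lists. Pes1 was at -1.72, Utp20 and Grwd1 at -1.30 each and Pno1 at -1.23, and Myc itself at -0.71 ± 0.20. The other probe of Pes1 gave -0.73. Glycolysis genes had a median of 0.45, above all random lists, with 8 of 24 at least 2-fold higher and none lower. The aldolase gene Aldoc (2.77), the glucose transporter gene Slc2a3 (2.28) and the enolase gene Eno2 (1.80) led them. Bnip3 (1.93), which this list also holds, is a mitophagy gene and does not encode a glycolysis enzyme. Genes of the amino acid stress response and serine synthesis had a median of 0.93, also above all random lists, with 8 of 23 at least 2-fold higher, led by Trib3 (2.80), the asparagine synthetase gene Asns (2.28), Chac1 (2.26) and Ddit3 (1.76). Sterol synthesis genes had a median of 0.46 (percentile 99.98), where Tm7sf2 (2.35) and Mvd (1.25) were the 2 of 23 past 2-fold. None of 34 oxidative phosphorylation genes differed by 2-fold (median -0.17, percentile 7.86).

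Among the helper T cell lists, type 2 genes were higher and type 17 and follicular helper genes lower as groups. Of 12 type 2 genes, 6 were at least 2-fold higher, among them Il4, the transcription factor gene Maf (2.80) and Il24 (2.53), while Il9 was lower (-3.19). The median was 0.99, above all random lists. With only the brighter measured genes, 6 type 2 genes were left, with a median of 0.45 at the 97.4 percentile, short of the limit. Of 12 type 17 genes, 7 were at least 2-fold lower, among them Il22 (-4.33), but Il17a (3.38) and Ltb4r1 (3.68) were higher. Their median was -1.17, below all random lists. With only the brighter measured genes, 4 type 17 genes were left, with a median of -0.30 at the 17.3 percentile. Of 11 follicular helper genes, 4 were at least 2-fold lower, led by the transcription factor gene Bcl6 (-3.95) and Pou2af1 (-2.44), and 2 higher, Ascl2 (2.26) and the receptor gene Pdcd1 (1.42), for a median of -0.63 (percentile 0.09). Bcl6 was at -3.08 and Ascl2 at 1.02 with normexp. The B cell marker list, with a median of -1.74, was lower on the same array. Type 1 genes had a median of 0.00 (percentile 68.7), with Cxcr6 at 2.73, Eomes at -3.84 and Ccl3 at -1.28. Counting members above background on either array gave a median of 0.27, at the 98.0 percentile.

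Cytotoxic granule genes were higher, 6 of 10 by at least 2-fold and 1 lower, Serpinb9 (-1.63, named as the exception), with a median of 1.42, above all random lists. Besides Gzmb, the death ligand gene Fasl was 7.94-fold higher, Nkg7 4.92-fold and Gzma, which encodes granzyme A, 3.48-fold. The CD8 T cell list had a median of 0.49 over 5 genes (percentile 91.2), in which Klrc1 was higher (3.65) and Eomes lower (-3.84). Klrc1 was at 1.96 and Eomes at -2.89 with normexp. The natural killer cell list had a median of -0.83 over 5 genes (percentile 0.46), with Gzma at 1.80, Tyrobp at -1.50 and Fcer1g at -1.25. Without a filter on dim genes its median was -0.26, at the 8.0 percentile, and with only the brighter measured genes 2 were left, with a median of 0.77. Among receptor genes of these cells, Klrd1 and Klrk1 were above background only on the co-culture array, with log2 bounds of 2.21 and 1.42, whereas Ncr1 and Klra8 were above it only on the naive-only array, with log2 bounds of -1.25 and -0.65, and Klra1 was at -0.83. The T cell receptor gamma constant region probe (chromosome 13, 19444153 to 19444212) was at 4.23. Its naive-only level of -3.45 was near the lowest level above background on that array (-4.03). A nearby probe, at 19443911 to 19443970, was at 1.51. These genes and probes were named after their values were seen.

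Genes linked to T cell anergy were higher as a list. The median over 21 genes was 0.47 (percentile 99.95), with 6 at least 2-fold higher and 1 lower, Ikzf1 (-1.38, named as the exception). The phosphatase gene Ptpn22 (2.30), the mTOR inhibitor gene Ddit4 (2.12), Nfil3 (1.86) and the ubiquitin ligase gene Nedd4 (1.60) led them. The ubiquitin ligase genes Cblb and Rnf128 stood at -0.31 ± 0.20 and 0.86 ± 0.22, the transcription factor gene Egr2 at -0.35 ± 0.20, and Egr3 was not well above background on either array. Regulatory T cell genes had a median of 0.51 over 19 genes, above all random lists, but the bootstrap interval over genes was -0.28 to 0.94. Il10, the receptor gene Tigit (1.67), the inhibitory receptor gene Ctla4 (1.12) and the Helios gene Ikzf2 (1.03, or 0.98 with normexp) were at least 2-fold higher. None of the 19 was at least 2-fold lower. Gpr83 was above background only on the naive-only array (log2 bound -1.91) and Entpd1 only on the co-culture array (log2 bound 1.83). Both were named after their values were seen. Foxp3, which encodes the lineage's defining transcription factor, was at -0.39 ± 0.21, and the interleukin 2 receptor gene Il2ra at 0.51 ± 0.20. The co-inhibitory list holds genes of receptors and of some ligands. Of its 14 measured genes, 5 were at least 2-fold higher, all of them receptor genes. These were Tigit, Lag3 (1.53 ± 0.20), Pdcd1 (1.42), Havcr2 (1.33) and Ctla4. The 3 lower were the receptor gene Btla (-1.74) and the ligand genes Cd274 (-1.51) and Cd200 (-1.10). Havcr2 and Cd200 were named after their values were seen. The list median was 0.40 (percentile 99.53), but with only the brighter measured genes it was -0.039.

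T cell activation genes were lower as a list, with a median of -0.45 (percentile 0.02), 9 of 25 at least 2-fold lower and 1 higher, Zbtb32 (1.82, named as the exception). The early activation marker gene Cd69 was 5.84-fold lower (-2.55 ± 0.20), the ligand genes Tnfsf11 and Cd40lg 5.57-fold and 4.58-fold lower, and the transcription factor gene Rel 4.45-fold lower. Cd40lg was 2.65-fold and Rel 2.06-fold lower with normexp. Genes of naive and quiescent T cells were lower too, with a median of -0.49, below all random lists, 7 of 24 at least 2-fold lower and 3 higher. Bach2 (-2.45), the lymph node homing receptor gene Ccr7 (-2.40) and Igfbp4 (-2.38) were lower, whereas the interleukin 7 receptor gene Il7r (1.76), Txnip (1.13) and Pik3ip1 (1.07), the last 2 named after their values were seen, were higher. The B cell marker list moved the same way as both of these lists. Immediate-early and heat shock genes had a median of -0.33 (percentile 0.94), with Jun at -1.57, Zfp36 at -1.16 and Ier3 at 1.46. T cell receptor signalling genes had a median of 0.20 (percentile 99.69), and only Cd6 (-1.16) of 29 passed 2-fold. Cd4 was at 0.35 ± 0.20 and Cd3e, a subunit of the T cell receptor complex, at 0.37 ± 0.20.

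Interferon-stimulated genes were lower, with 19 of 35 measured members at least 2-fold lower and 1 higher, Ly6a (2.3-fold, named as the exception). Oasl1 was 22.5-fold lower, Ifi44 15.6-fold, the ubiquitin-like modifier gene Isg15 12.7-fold and Rtp4 12.2-fold. Another 5 members were above background only on the naive-only array. The median was -1.42, or 2.67-fold lower, below all random lists. B cell markers, at a median of -1.74, were lower on the same array.

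Markers of B cells and of class II antigen presentation had the lowest medians among the markers of other cell types. Of 14 measured B cell genes, 13 were at least 2-fold lower, led by Ms4a1 (32.7-fold), Spib (11.0-fold), the IgE receptor gene Fcer2a (7.26-fold) and Bank1 (6.26-fold). The other, Fcmr, was higher at 1.33 and is named as the exception among the 14. Ms4a1 was 20.9-fold, Spib 6.68-fold and Fcer2a 2.90-fold lower with normexp. The median of the 14 was -1.74, or 3.35-fold lower. Another 2 B cell genes were above background only on the naive-only array and 1 only on the co-culture array. Of 9 class II genes, 6 were at least 2-fold lower, with H2-Aa, H2-Eb1 (-3.12), the invariant chain gene Cd74 (-2.79) and H2-DMb1 (-2.18) in front, and the median was -1.35. Both medians lay below all random lists. Plasma cell genes had a median of -0.43 (percentile 3.19), with Jchain (-3.20) and Mzb1 (-1.46) lower and Prdm1 (1.84) and Xbp1 (1.15) higher.

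Other blood cell markers were mixed. Dendritic cell genes had a median of -0.86 (percentile 0.02), with Fscn1 (-4.56), Flt3 (-2.87) and Tcf4 (-1.53) lower and Batf3 (3.51) higher. Fscn1 was at -3.62 and Flt3 at -1.47 with normexp. With only the brighter measured genes, 4 were left, with a median of -0.41 at the 8.54 percentile. Macrophage and monocyte genes had a median of -0.40 (percentile 1.28), with 6 of 15 at least 2-fold lower, led by Mpeg1 (-2.75), Apoe (-1.83), Cd14 (-1.71) and Clec4d (-1.24), and 1 higher, Hmox1 (1.18, named as the exception). Erythroid genes had a median of -1.26 (percentile 0.03), led by Car2 (-2.78) and Tspan33 (-2.23), with the globin genes Hba-a2 at -1.34 and Hbb-b2 at -1.26. Car2 was at -1.48 and Hbb-b2 at -0.52 with normexp. Without a filter on dim genes the erythroid median was 0.057. Basophil and mast cell genes had a median of -1.28 over 3 genes (percentile 0.95), namely Il4, Il6 (-3.20) and Hdc (-1.28), and a median of 0.11 without that filter. The neutrophil list had a median of 0.21 (percentile 86.4), in which Ly6g stood apart from Lcn2 (1.29), Camp (-1.51) and Chil3 (-1.42). Platelet genes had a median of 0.44 over 4 genes (percentile 90.2), with Itgb3 and Pf4 at 1.14 each. The other probe of Itgb3 gave 0.45, and Pf4 was at 0.61 with normexp background correction. Stromal and endothelial genes had a median of 0.19 over 5 genes (percentile 74.9), and 2 more, Col1a2 and Pdgfrb (named after its value was seen), were above background only on the naive-only array.

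Apoptosis genes showed no shift as a list (median -0.10, percentile 34.3), with Fasl (2.99) higher and Bcl2l11 (-2.41), Cflar (-1.81) and the death receptor gene Fas (-1.40) lower. The other probes of Bcl2l11 and Cflar gave differences as small as -0.90 and -0.76. The p53 targets had a median of 0.05 (percentile 74.0), with the cell cycle inhibitor gene Cdkn1a (2.32), Gtse1 (2.05), Bbc3 (1.39) and Sesn2 (1.32) higher. Housekeeping genes had a median of -0.03 (percentile 78.8), and none of 16 passed 2-fold.

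**Figure D3:**
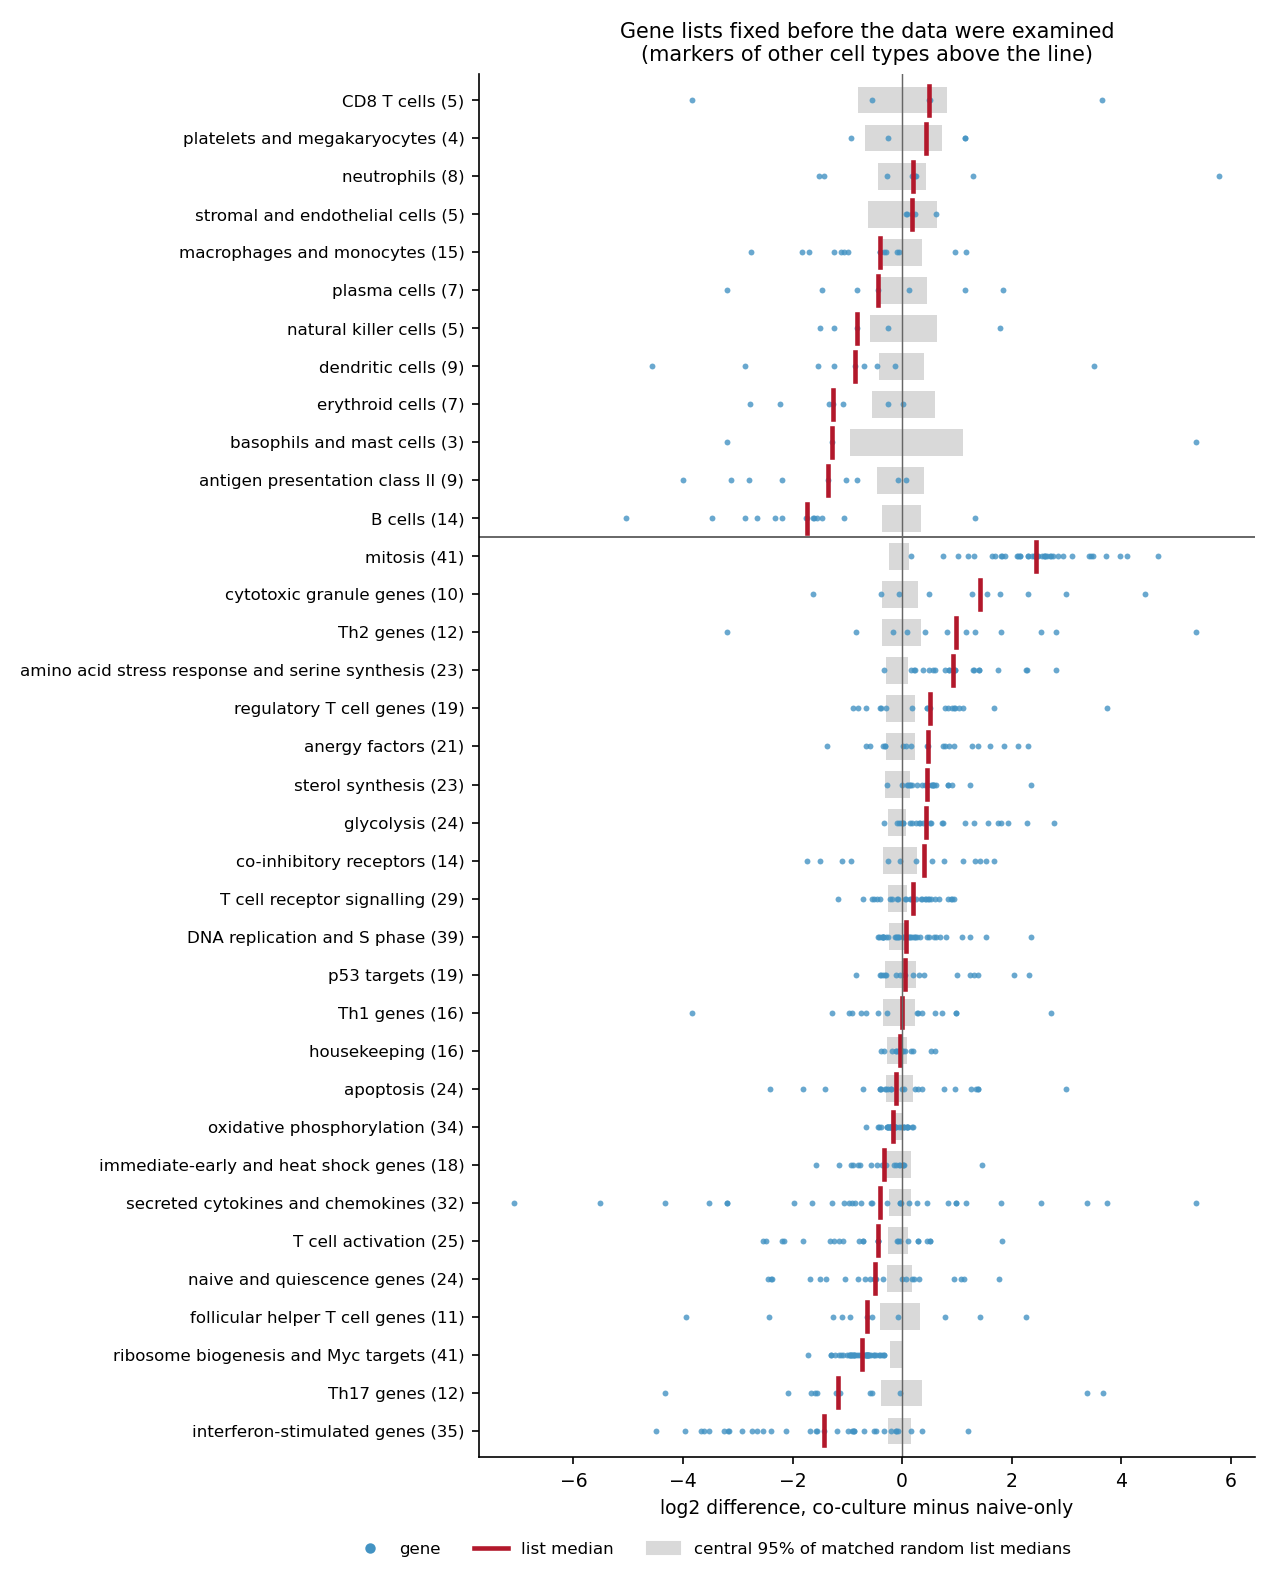
Log2 difference (co-culture minus naive-only) of each measured member (points) and the median (red line) of the 36 gene lists, with the number of measured members in brackets. Grey bars hold the central range of medians of 10000 matched random lists. Mitosis lies at 2.44, interferon-stimulated genes at -1.42 and B cells at -1.74.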

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

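The filter that kept only genes at or above the median level of the measured genes was chosen after seeing the data, and all other alternatives were planned. No paired analysis was possible because each group has 1 array and the result comes from no test. The 3 alternatives that filter genes leave the value of a named gene as it is; under the others, all 1072 pairs of a named gene and an alternative kept the sign of the difference, and 14 pairs, of 10 genes, crossed 2-fold: Camp, Chil3, Clec4d, Hbb-b2, Hdc, Ikzf2, Pf4 and Zfp36 were under it with normexp and Itgb3 with the mean over probes, and Ifng was over it in 5 alternatives. The difference moved by more than its technical error in 60 genes with normexp, 31 of them by over 1.5 times in fold, and in 7 with the mean over probes, 2 of them (Bcl2l11 and Cflar) by over 1.5 times. All 10 printed bounds moved with normexp, by a median of 3.55 times, and none moved under the other alternatives that give one. The planned stricter filter removed no gene and is left out of the next count. In 417 of 429 pairs of a list and an alternative, the direction and the side of the percentile limits were kept. Without a filter on dim probes, 27665 genes entered and 2458 were higher and 2155 lower, many with differences set by background. With only the 7189 brighter genes, 363 were higher and 193 lower, out of fewer genes. With normexp, 797 were higher and 529 lower; its offset shrinks differences of dim genes by construction. Under the other alternatives the counts stayed between 1091 and 1197 higher and between 735 and 806 lower.

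With only the brighter genes, the medians were -0.039 for co-inhibitory receptors and ligands, 0.45 for type 2 genes (6 members, percentile 97.4) and -0.30 for type 17 genes. They were -0.045 for cytokines, -0.41 for dendritic cells and 0.77 for natural killer cells (2 members). Fewer members were left in each of these lists. Without a filter, the medians were -0.26 for natural killer cells, 0.057 for erythroid cells and 0.11 for basophils and mast cells, where undetected members entered. Counting members above background on either array put type 1 genes at 0.27 (percentile 98.0). Unmatched random lists put the S phase median of 0.071 at percentile 89.2, and normexp put plasma cells at -0.46 (percentile 2.22); the cause was not tested for these 3. Among named genes, 11436 were below background on both arrays and have no difference. For several lists called apart, the bootstrap interval over members held both signs. Those called higher included co-inhibitory (-0.68 to 1.27), type 2 (-0.04 to 2.17) and cytotoxic granule genes (-0.05 to 2.39). Regulatory T cell, S phase and T cell receptor signalling genes did so too. Those called lower included follicular helper (-1.27 to 0.79), cytokine (-0.96 to 0.27) and naive genes (-0.81 to 0.07). Natural killer and basophil genes, with few members, did so too.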

Other observations

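The tests on S phase genes, immunoglobulin probes, myeloid markers and the share of interferon genes below B cell genes were chosen after the results were seen, and the hypoxia and STAT5 lists were added then, with their limits set before their values were computed.

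Probes for T cell receptor variable segments were examined on both arrays, with no test of alpha against beta. Of 19 alpha variable probes above background on at least 1 array, 15 were above it on both and 2 only on each, with alpha segment 4D-3 at least 4.70-fold higher on the co-culture array. Of 17 beta variable probes above background on at least 1 array, 9 were above it on both, 8 only on the co-culture array and none only on the naive-only array. The probe for beta variable segment 23 was at least 7.05-fold higher on the co-culture array, that for segment 19 at least 4.24-fold and that for segment 31 at least 3.73-fold, but those for segments 15, 13-2 and 29 had bounds of only 1.28-fold, 1.45-fold and 1.48-fold, and another probe for 13-2, measured on both, was at 0.11. Variable segment 1, measured on both, was 7.29-fold higher. Segment 12-2 was at -0.75, the Vb17a probe at -0.51 and segment 20 at -0.45, and the constant regions 1 and 2 were at -0.06 and -0.19. By level, segment 20 was the brightest beta variable probe, with 5.04 on the naive-only and 4.58 on the co-culture array. The next brightest, for segment 5, had levels of -0.75 and -0.53. Segments 23, 19 and 31 were dim, with naive-only levels of -6.23, -4.74 and -3.94. Their co-culture levels were -1.21, -1.94 and -2.05, far below that of segment 20. The receptor gamma constant region was at 4.23, and a nearby probe on chromosome 13 at 1.51. These probes were named after their values were seen, and whether similar segments share a probe was not examined. Immunoglobulin probes went the other way, with a median of -2.76: 62 were above background on both arrays, 61 of them lower on the co-culture array, and another 56 were seen only on the naive-only array.

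Hypoxia targets were examined because the genes of the glycolysis list with the largest differences are also induced by low oxygen. A list of 21 other measured hypoxia targets had a median of 0.60, at the 99.99 percentile of matched random lists, with 5 at least 2-fold higher and 1 lower. Car9 (2.18), Vegfa (1.80) and P4ha2 (1.52) were higher and Adm (-2.85) lower, all named after their values were seen. In the glycolysis list itself, 20 of 24 genes were positive and 4 negative. The negative ones included Ldha (-0.09), Hk2 (-0.06) and Pfkfb3 (-0.33), named after their values were seen, which low oxygen can also induce. A stronger hypoxia response in the co-culture sample is a candidate explanation, and other causes of these differences were not tested. Cell density and oxygen were not measured here. Another hypothesis was that the low Il2 level went with weaker signalling through STAT5, the factor that interleukin 2 activates. A list of 18 STAT5 targets had a median of -0.12, at the 33.52 percentile, and 9 members were positive and 9 negative, so this list decides nothing.

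The mitosis genes were higher on the co-culture array by a median of 2.44. Between-array scaling or a signal-dependent bias is argued against, since the lowest median over 6 other scalings, backgrounds and the deposited values was 2.28. A larger cycling share with the same mix of phases might raise S phase genes too. Their median was 0.071 (bootstrap interval over genes -0.05 to 0.24), below the bound of 1.22 by more than the SD of 0.58 among these genes. As a list, S phase genes thus rose far less than mitosis genes. The bound was set after both medians were known, and how far such a share would raise S phase genes was not measured. The comparison therefore cannot decide between a larger cycling share and a different mix of phases. Cells pre-stimulated with TSST-1 that were sorted with the naive ones, and an effect on the naive cells themselves, both stay open and untested.

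B cell and class II genes were lower on the co-culture array, although CD4 sorting should remove B cells from both samples. Fewer B cells among the sorted cells is consistent with the immunoglobulin median of -2.76, in a class of probes that neither list holds. A lower share of all cells other than T cells stays open too. The median of 19 monocyte, macrophage and neutrophil markers was -0.40 against -1.74 for B cells. Its bootstrap interval over markers, -1.24 to 0.18, lay above the B cell median. The markers went both ways (13 negative, 6 positive), and their SD of 1.79 exceeded the gap between the medians. Without Ly6g, which rests on 1 probe in a family of similar genes, the median stayed at -0.40. The SD was then 1.06, less than the gap. By median these markers thus fell less than the B cell genes, but the other lists disagree. Dendritic (-0.86) and erythroid (-1.26, but 0.057 without a filter on dim genes) medians were lower, while platelet (0.44) and stromal (0.19) medians were not, though the stromal genes Col1a2 and Pdgfrb were detected only on the naive-only array. Cd74 went from 5.74 to 2.95 and Ms4a1 from 3.52 to -1.51, and no gene of either list is in another list; how many of them T cells also express, fewer B cells in the co-culture itself and a cleaner sort were not tested.

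Interferon-stimulated genes were lower by a median of -1.42. The highest median over 6 other scalings, backgrounds and the deposited values was -0.99, narrowly short of the limit of -1 set before it was computed. That value came with normexp, whose offset shrinks differences of dim genes by construction. The other scalings and the deposited table moved the median over all measured genes by at most 0.055 (log2). This argues against scaling as the source of a shift of -1.42. A part played by background could not be ruled out by that test. Loss of B cell RNA alone stays open as well. Of 35 members, 7 (20%) were lower than the B cell lower quartile of -2.57 by over 2 technical errors. The same held for 2 of 14 B cell genes and 20 of 62 immunoglobulin probes. This comparison decides nothing, because few B cell genes can lie below their own lower quartile. It also left out 5 interferon members and 56 immunoglobulin probes that were above background only on the naive-only array. A weaker interferon response of the T cells, and a smaller interferon source in the culture, stay open and untested.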
